A study of Mus musculus with 47 samples.

How the data were processed

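RNA was measured in sorted mouse cortical nuclei (12 bulk libraries and 1357 single-nucleus SMARTseq2 libraries), in cultured cortical neurons (6 libraries), in PU.1-sorted nuclei (9 libraries) and in 7 brain sections on spatial capture slides. A section of a further CK mouse, replicate 4, was not analysed here. Per the labels, bulk gate libraries were made from nuclear RNA with a SMARTer stranded total RNA kit 2 weeks after induction. The submitters' processing notes list cutadapt 1.16, Trim Galore 0.4.5, Salmon 0.12.0, R 3.6.1, BWA, SAMtools and HTSeq with builds GRCm38, GRCh38 and mm10 for the samples that are not spatial, and Scanpy 1.7.2 with mm10 for the spatial ones. Which tool and build served which file is not given in the sources used here.

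The values of the bulk gates were TPM as deposited, although the table is named for counts. They are not whole numbers and sum to 984472 to 993810 per library. The deposited values of cultured neurons, PU.1-sorted nuclei, single nuclei and spots were whole-number counts per gene. The cell labels, the flag for p25 and the mark for DNA damage are the authors' deposited annotation, and how they were made is not given in the sources used here. The deposited annotation also gives the percent of mitochondrial UMIs per spot, as the authors computed it, with section medians of 8.25% to 13.6%. Genes higher in marked spots may include those used to set the mark. Gene identifiers were paired with symbols for 48322 of 48457 in the bulk gates, 55154 of 56196 in the cultured neurons and 54392 of 54460 in the PU.1-sorted nuclei. Cdkn1a was not analysed here in the bulk gates, where no identifier paired with it.

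Groups came from the labels. The tests, gene lists, naming rule and the first set of alternative settings were chosen before the data were examined. Count tables were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, its default filter on low counts by group, Benjamini-Hochberg adjusted p under 0.05), in R 4.3.3. A count test had also been planned for the bulk gates. As their unit was TPM, limma 3.58.1 with a trended prior was used on log2 of scaled TPM plus 1, for genes at 1 TPM or more in at least 2 libraries, with TMM-type scaling factors and all 12 libraries in the fit. DESeq2 1.42.0 served as an alternative on counts and was not run on TPM. In the bulk gates all groups shared 1 estimate of the spread, and depth could not be read from TPM.

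Single nuclei were summed over the 1008 of 1357 that passed the authors' quality control, per mouse and gate, with sums of under 5 nuclei to be left out (there were 0). No doublet caller was run, as each library came from 1 sorted nucleus. The time point was a covariate, and the mouse was a block for Stage 2 against Stage 1. Spots over tissue were summed per section, and per authors' cluster where at least 3 sections of each genotype had 20 or more spots. Clusters were named by their leading genes in CK sections, and no cell-type makeup was estimated. Marked spots were compared with unmarked spots of the same section drawn to match their clusters, 255 to 359 per section, with the section as a block.

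For each comparison the 27 gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over lists and comparisons of a dataset. Named genes were the 10 largest rises and the 10 largest falls among called genes with an average log2 CPM of at least 3 and no overlap between libraries of the groups. To these came up to 4 members of each list described, those with the largest change among called members or else the most abundant, and 15 genes fixed in advance. Some genes that met this rule are not reported here. Genes named outside this rule are said to be chosen after their values were seen. Label shares and spot correlations were tested by exact permutation with the mouse as the unit. The reversal share was set beside 100 simulations of unchanged libraries labelled knockdown that share the scramble libraries.

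Each procedure was tested on simulated data with 200 changed genes drawn from the real means and library sizes. At 4-fold, edgeR recovered 96.7% of changed genes in the cultured neurons, 87.3% in libraries labelled knockdown against scramble and 98.5% in whole sections, and limma 71.6% in bulk Stage 1. In single-nucleus sums edgeR recovered 11.1% in Stage 1 and 9.38% in Stage 2 at 4-fold, and 92.7% and 82.5% at 32-fold. Labels name separate mice for the single nuclei and sections. For the bulk gates the series' design has each gate sorted from 2 mice per genotype, so gates of 1 genotype share animals, but no label ties a replicate number to a mouse. The fit took the 12 libraries as independent, and alternatives blocked the number, or the genotype and number together as the mouse. For the cultured neurons and PU.1-sorted libraries the design calls the replicates biological and names no separate cultures or animals, so p-values measure the spread between these libraries, which may be technical.

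Sections with the same replicate number deviated together from their group means (correlations of 0.489 to 0.807 over 3 pairs), and the replicate number was used as a block in an alternative fit. For CK sections 1 and 2 a CK-p25 section of another number correlated more, at 0.660 and 0.768, against 0.573 for CK section 3. The numbers are therefore not shown to be pairs. Sections lay on 2 slides, which held both genotypes. Alternatives covered scaling, the low count filter, the tool, the pseudocount, the reference gate, the time point, the replicate block, the slide, and leaving out each library, mouse or section. Single-nucleus fits without the CK 2 week mice, without nuclei labelled Batch and in nuclei labelled excitatory, TPM without scaling, the reversal share with a block, the spot relation in pairs or in unmarked spots, and all comparisons of marked and neighbouring spots were added after seeing the data. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the remaining work.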

Results

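RNA was measured in the CK-p25 mouse, in which forebrain excitatory neurons make p25, a fragment that activates the kinase CDK5, once doxycycline is taken out of the diet, and in CK control mice. The study asks how neurons that carry DNA double-strand breaks relate to the activation of microglia. Cortical nuclei were sorted by staining for NeuN, a nuclear protein of neurons, and γH2AX, a histone mark laid down at double-strand breaks, into gates called baseline, Stage 1, Stage 2 and glia. Bulk RNA of these gates came from 2 CK-p25 and 2 CK mice, as 12 libraries in 6 groups of 2. Single nuclei of the same kinds of gate came from 12 mice, 3 per genotype at 1 week and 3 per genotype at 2 weeks after induction. Cultured cortical neurons on day 12 in vitro received 50 µM etoposide, a topoisomerase II poison that breaks DNA, or its solvent DMSO for 6 hours (3 libraries each). Microglial nuclei were sorted by PU.1, a transcription factor of the myeloid lineage, from CK mice given PBS, CK-p25 mice given a scrambled control and CK-p25 mice labelled as having a knockdown of the NF-kB subunit p65, which the gene Rela encodes (3 libraries each). Spatial transcriptomes covered brain sections of 4 CK-p25 and 3 CK mice.

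The bulk gate values were TPM, a length-normalised relative abundance, so their depth is unknown. Totals were 45455744 to 65276092 counts in the cultured neurons, 10589274 to 20629337 in the microglia libraries, 107325 to 848544 in the 36 sums of single nuclei per mouse and gate, and 26785432 to 43100103 UMIs per section. The sums held 14 to 48 nuclei each. A section had 2303 to 2624 spots with a median of 8805 to 15377 UMIs. Fold changes are log2 values ± SE. In bulk gates they were taken after adding 1 to the TPM, which understates the change of low genes.

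Stage 1 neurons of the bulk gates carried higher RNA of replication, cell-division and damage-response genes than CK baseline neurons, and lower RNA of synaptic genes (n = 2 libraries each). Mcm3, a subunit of the replicative helicase, rose by 5.38 ± 0.14, from 0.225 to 49.9 TPM, and Mki67, a marker of dividing cells, by 4.22 ± 0.15, from 0.141 to 20.3 TPM. Pmaip1, a p53 target that promotes cell death, rose by 4.13 ± 0.15, and Egr1, a gene switched on by neuronal activity, by 2.95 ± 0.15. Syt1, the calcium sensor of synaptic vesicles, fell by 1.44 ± 0.11, from 308 to 113 TPM. With limma, 8180 of 24367 genes had an adjusted p under 0.05, 4858 higher and 3322 lower.

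Of 25 cell cycle genes, 24 rose and 0 fell in Stage 1 (24 adjusted over the list alone), among them the helicase genes Mcm5, at 4.29 ± 0.13, and Mcm2, at 3.86 ± 0.22. Of 29 p53 and damage-response targets, 22 rose and 2 fell (25 calls adjusted over the list alone). They included Pidd1, which assembles a caspase-activating complex (3.87 ± 0.31), Phlda3, an inhibitor of AKT (3.36 ± 0.16), Trp53inp1 (3.33 ± 0.14) and the death effector Bbc3 (2.85 ± 0.33). Of 31 break-repair genes, 19 rose and 1 fell (20 adjusted over the list alone), with the recombination gene Brca1 at 4.35 ± 0.37 (limma; camera adjusted p = 0.057 with an estimated correlation). Of 18 immediate early genes, 10 rose and 1 fell (12 adjusted over the list alone), including Btg2 (2.82 ± 0.11) and the AP-1 subunit Jun (2.74 ± 0.16), with a camera adjusted p of 0.11 under an estimated correlation. Among 18 death effectors, 9 rose and 1 fell (11 adjusted over the list alone; camera adjusted p = 0.16 with an estimated correlation).

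The interferon and antiviral list had 24 of 35 genes higher and 0 lower than in CK baseline (28 adjusted over the list alone). The GTPases Gbp3 and Mx2 rose by 2.26 ± 0.14 and 2.09 ± 0.15, and the antiviral gene Oasl2 by 1.92 ± 0.14. Against the CK-p25 baseline gate the direction turned for Mx2 at -0.46 and Oasl2 at -0.45, with limma adjusted p of 0.048 and 0.041. Tap1, the peptide transporter of antigen presentation, rose by 2.62 ± 0.16, in a list with 8 of 18 genes up and 0 down (8 adjusted over the list alone; camera adjusted p = 0.27 with an estimated correlation).

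Of 32 synapse and ion channel genes, 25 fell and 1 rose (26 adjusted over the list alone), with Syp, a vesicle protein, at -1.21 ± 0.14 and the adhesion gene Nrxn3 at -1.20 ± 0.18. Markers of inhibitory neurons fell in 9 of 11 cases and rose in 0 (10 adjusted over the list alone), led by Vip at -2.92 ± 0.20 and Adarb2 at -2.32 ± 0.12 (camera adjusted p = 0.09 with an estimated correlation). Markers of excitatory neurons fell in 9 of 12 cases and rose in 0 (10 adjusted over the list alone), with the vesicular glutamate transporter Slc17a7 at -1.26 ± 0.13 and Rorb at -1.63 ± 0.16. Rbfox3, which encodes NeuN, fell by 0.86 ± 0.25, from 128 to 69.8 TPM (limma, adjusted p = 0.031). Markers of other cells moved too. The astrocyte filament gene Gfap rose from 1.13 to 6.31 TPM, C1qa by 0.71 ± 0.23, and Spi1, which encodes PU.1, stood at 2.07 TPM in Stage 1 and was listed at 0 in CK baseline. Of 20 homeostatic microglia genes, 6 rose and 0 fell (7 adjusted over the list alone; limma), and the list was not called (camera, preset correlation, adjusted p = 0.095), with 3 higher without scaling. The count of called genes was 4867 without Stage 1 replicate 1 and 4444 without Stage 1 replicate 2. Without scaling between libraries, 4462 genes were higher and 1544 lower, with the median of all genes at 0.11.

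**Figure D1:**
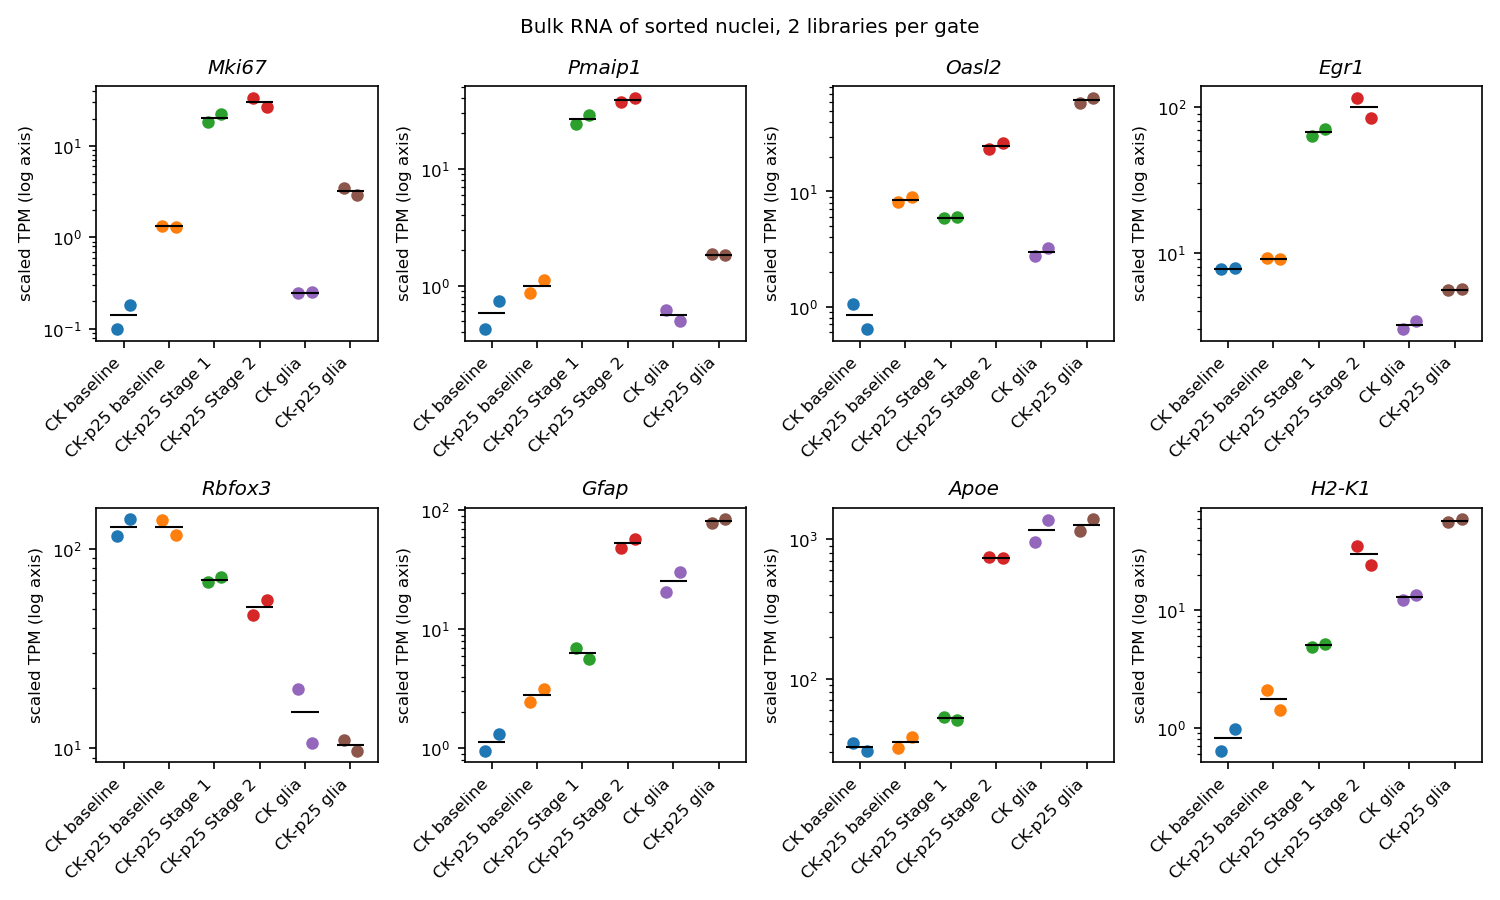
Scaled TPM (log axis) of 8 genes in the 12 bulk libraries of sorted nuclei. Points are libraries, 2 per gate, and lines are means. Mki67 and Pmaip1 were higher in both Stage 1 and both Stage 2 libraries than in the CK baseline libraries. In Stage 2 Oasl2, Gfap, Apoe and H2-K1 lay below CK-p25 glia, and the others above.

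Stage 2 nuclei had higher replication, p53 and interferon RNA than CK baseline nuclei, together with higher RNA of glia, vessels, mitochondria and ribosomal proteins (n = 2 libraries each). Mcm3 rose by 5.47 ± 0.14 and Mki67 by 4.78 ± 0.15, to 30.4 TPM. Xaf1, an interferon-induced promoter of apoptosis, rose from 7.9 to 466 TPM, by 5.71 ± 0.19. Apoe, the lipid carrier made mostly by glia, rose from 32.6 to 738 TPM, by 4.46 ± 0.18, and Slco1a4, a transporter of brain endothelium, from 0.468 to 80.5 TPM. Limma called 7314 genes higher and 6102 lower.

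All 25 cell cycle genes rose (25 adjusted over the list alone). Of 29 p53 targets, 24 rose and 3 fell (27 adjusted over the list alone), with Phlda3 at 4.65 ± 0.16, Pmaip1 at 4.66 ± 0.15 and Bbc3 at 4.02 ± 0.33. Interferon genes rose in 32 of 35 cases and fell in 0 (32 adjusted over the list alone), including Ifit3 at 4.12 ± 0.16 and Gbp3 at 3.73 ± 0.14. The chemokine gene Cxcl10 stood at 4.28 TPM and was listed at 0 in CK baseline. Antigen presentation genes rose in 14 of 18 cases and fell in 0 (14 adjusted over the list alone), with the class I genes H2-T23 at 4.72 ± 0.16 and H2-K1 at 4.08 ± 0.20 and their light chain B2m at 3.02 ± 0.17 (camera adjusted p = 0.087 with an estimated correlation). Class I genes are near copies of one another, so their separate values are uncertain.

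Mitochondrially encoded RNAs, which are not nuclear transcripts, rose in 11 of 13 cases and fell in 0 (11 adjusted over the list alone), with mt-Cytb at 2.93 ± 0.12, from 80.3 to 616 TPM. Cytosolic ribosomal protein genes rose in 23 of 23 (23 adjusted over the list alone), with Rps2 at 3.01 ± 0.18 (camera adjusted p = 0.188 and 0.155 for the 2 lists, with an estimated correlation). Without scaling 11 and 20 of them were higher and 0 lower, with medians of 2.05 and 1.33.

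Markers of other cell types rose in Stage 2, so glia as a source of interferon and class I RNA stay open. Endothelial and mural markers were higher in 12 of 12 cases (12 adjusted over the list alone), with the pericyte gene Rgs5 at 4.22 ± 0.16. Oligodendrocyte markers were higher in 11 of 12 and lower in 1 (12 adjusted over the list alone), with the myelin genes Mobp at 3.28 ± 0.22 and Mbp at 2.58 ± 0.11. Astrocyte markers were higher in 10 of 11 and lower in 1 (11 adjusted over the list alone), with Aldoc at 3.23 ± 0.17, and Gfap, of the reactive astrocyte list, at 4.66 ± 0.20. Homeostatic microglia genes were higher in 18 of 20 and lower in 1 (19 adjusted over the list alone), with the complement gene C1qa at 3.45 ± 0.23, but without scaling 11 were higher and 1 lower. Synapse genes fell in 22 of 32 cases and rose in 3 (27 adjusted over the list alone), with Nrxn3 at -2.0 ± 0.18 and the potassium channel Kcnma1 at -1.99 ± 0.11, while Vamp2, a vesicle fusion protein, rose by 1.78 ± 0.08 (camera adjusted p = 0.13 with an estimated correlation). Rbfox3 fell by 1.31 ± 0.25 to 50.8 TPM, and Cdk5r1, the parent gene of p25 and not told apart from it, rose by 1.14 ± 0.15. The library scaling factors spanned 0.527 to 1.37, lowest in both Stage 2 libraries. Without scaling, 3438 genes were higher and 9603 lower, with the median of all genes at -0.43.

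Genes of vessels, myelin, phagocytes and mitochondria were among those that rose from Stage 1 to Stage 2. Slco1a4 rose by 5.13 ± 0.24, Mobp by 3.00 ± 0.22 and Apoe by 3.80 ± 0.18, from 52 to 738 TPM. The phagocyte genes Cyba, an oxidase subunit, Ctss, a lysosomal protease, and Mertk, an engulfment receptor, rose by 3.55 ± 0.12, 2.72 ± 0.11 and 2.46 ± 0.11. Of 24 phagocytosis and lysosome genes, 19 rose and 1 fell (23 adjusted over the list alone). Oligodendrocyte markers rose in 11 of 12 cases and fell in 0 (12 adjusted over the list alone), homeostatic microglia genes in 16 of 20 with 1 lower (17 adjusted over the list alone), and interferon genes in 24 of 35 with 2 lower (27 adjusted over the list alone), with Cxcl10 at 1.96 ± 0.17. Without scaling, phagocytosis and lysosome genes had 9 higher and 1 lower, homeostatic microglia genes 9 and 2, and interferon genes 10 and 7. Endothelial and mural markers rose in 12 of 12 (12 adjusted over the list alone; camera adjusted p = 0.12 with an estimated correlation). Mitochondrially encoded RNAs rose in 11 of 13 and fell in 0 (11 adjusted over the list alone), with mt-Cytb at 3.32 ± 0.12 and mt-Nd5 at 3.34 ± 0.18 (camera adjusted p = 0.13 with an estimated correlation).

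The excitatory markers Nrgn and Camk2a were higher in Stage 2 than in Stage 1 by 2.18 ± 0.14 and 0.91 ± 0.11, and the vesicle gene Snap25 by 1.23 ± 0.09, but Camk2a turned to -0.03 without scaling. Of 12 excitatory markers, 8 rose and 0 fell (8 adjusted over the list alone), a direction that was lost without scaling, where 2 were higher and 2 lower with a median of -0.02 (camera adjusted p = 0.051 with an estimated correlation). The cell cycle list was not called (10 of 25 higher and 5 lower, 15 adjusted over the list alone, camera adjusted p = 0.2 with a preset correlation), and it had 1 higher and 11 lower without scaling. Nor were the synapse list (11 of 32 higher and 13 lower, 24 adjusted over the list alone, camera adjusted p = 0.90 with a preset correlation) and the repair list (6 of 31 higher and 6 lower, 12 adjusted over the list alone, camera adjusted p = 0.97), which without scaling had 1 higher and 21 lower, and 2 higher and 21 lower. Limma called 5911 genes higher and 6036 lower. Without scaling 1617 were higher and 11584 lower, and the median of all genes was -0.69.

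The baseline gate of CK-p25 mice held higher interferon and replication RNA than that of CK mice. Mx2 rose by 2.55 ± 0.15, from 0.931 to 10.3 TPM, Oasl2 by 2.37 ± 0.14 and Gbp3 by 1.97 ± 0.14. Interferon genes were higher in 10 of 35 cases and lower in 0 (22 adjusted over the list alone). Of 25 cell cycle genes, 9 rose and 0 fell (17 adjusted over the list alone), with Mcm3 at 2.62 ± 0.14, Mcm2 at 2.71 ± 0.22, Mcm5 at 2.46 ± 0.13 and the polymerase clamp Pcna at 2.00 ± 0.15. Of 31 repair genes, 2 rose and 0 fell (5 adjusted over the list alone), namely the break-signalling scaffold Mdc1 at 1.52 ± 0.12 and the exonuclease Exo1 at 1.65 ± 0.25. Outside the lists, the helicase gene Rad54b rose by 3.31 ± 0.29 and the checkpoint mediator Clspn by 2.29 ± 0.22, while Cntfr, a cytokine receptor subunit, fell by 1.06 ± 0.15.

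In the same gates no p53 target passed the limma threshold (0 of 29, 0 adjusted over the list alone, 7 at an unadjusted p under 0.05; camera with a preset correlation, adjusted p = 0.13), nor did a synapse gene (0 of 32, 0 adjusted over the list alone, 2 unadjusted). Rbfox3 stood at 128 TPM in both. In all, 98 genes rose and 19 fell. The count of 117 became 49 with the mouse, taken as genotype and number, as a block, 65 without scaling, 67 without CK baseline replicate 2, 65 without CK-p25 baseline replicate 1 and 176 with a pseudocount of 0.1. Without scaling 6 interferon, 5 cell cycle and 0 repair genes were called higher.

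The glia gate of CK-p25 mice showed the broadest interferon change of the bulk comparisons with CK, counted as list members called. Of 35 interferon genes, 34 rose and 0 fell (35 adjusted over the list alone), with Oasl2 at 3.98 ± 0.14, from 3 to 62 TPM, the deubiquitinase-like regulator Usp18 at 3.64 ± 0.30 and Ifit3 at 3.22 ± 0.16. Antigen presentation genes rose in 9 of 18 cases and fell in 0 (14 adjusted over the list alone), with the class I regulator Nlrc5 at 3.95 ± 0.14, Tap1 at 2.26 ± 0.16, H2-D1 at 2.21 ± 0.17 and H2-K1 at 2.09 ± 0.20. Cxcl10 rose from 0.0239 to 9.37 TPM, by 3.32 ± 0.17, and Ccl2, a chemokine for monocytes, by 1.89 ± 0.25. They belong to the 28 NF-kB targets and cytokines measured, of which 7 rose and 0 fell (13 adjusted over the list alone).

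Reactive astrocyte genes rose in 4 of 14 cases and fell in 0 (6 adjusted over the list alone), with Gfap at 1.67 ± 0.20 and Serpina3n at 0.82 ± 0.13. Of 23 genes of disease associated microglia, 3 rose and 0 fell (7 adjusted over the list alone), namely Itgax at 2.65 ± 0.28, Clec7a at 1.42 ± 0.18 and Cst7, which was listed at 0 in CK glia. Trem2, the lipid receptor of microglia, was 12.6 against 12.9 TPM and Apoe differed by 0.14 ± 0.18, and neither passed the limma threshold. Of 25 cell cycle genes, 7 rose and 0 fell (18 adjusted over the list alone), with Mki67 at 1.74 ± 0.15 and Top2a at 1.53 ± 0.17. In the synapse list 1 of 32 genes fell and 0 rose (17 adjusted over the list alone), and outside the lists the adhesion gene Lingo2 fell by 0.87 ± 0.12. Limma called 196 genes higher and 57 lower. The total of 253 became 107 and 127 without CK glia replicate 1 or 2, 109 and 137 without CK-p25 glia replicate 1 or 2, and 107 with the mouse as a block. Without scaling the median of all genes was 0.14.

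The authors' labels of 1008 single nuclei show what the gates held. In CK-p25 mice 88.3% ± 5.65 of baseline nuclei and 86.0% ± 5.60 of Stage 1 nuclei were labelled excitatory neurons (SD, n = 6 mice), against 6.74% ± 6.81 of Stage 2 nuclei. Of Stage 2 nuclei 80.7% ± 17.3 carried a label called Stage 2, as did 6.08% ± 4.71 of CK baseline nuclei. Inhibitory labels made up 12.7% ± 8.88 of CK baseline nuclei and 0 of 162 Stage 2 nuclei (up to 1.85% by counting error). These 3 Stage 2 differences from CK baseline each had p = 0.00216, the smallest a two-sided exact permutation test allows (adjusted p = 0.0253, 35 tests). With 1 label per nucleus they are not independent. The Stage 2 label replaces a cell type and bears the gate's name, so labelling may set all 3. In Stage 1 and Stage 2 of the same mice the smallest exact p, 0.0313, was reached for excitatory and Stage 2 labels (adjusted p = 0.143). The CK baseline gate was itself mixed, with 62.7% ± 27.1 excitatory and 11.2% ± 18.7 oligodendrocyte nuclei. CK mouse 2 at 2 weeks had 25.9% neuronal labels in its baseline gate (95% exact binomial interval 11.1 to 46.3, counting error only) and 91.7% in its glia gate. Baseline and glia gates held 92.0% and 75.0% such labels in mouse 1, 45.5% and 31.25% in mouse 3, and 92.6% to 100.0% and 16.7% to 26.1% in CK mice at 1 week. In the CK-p25 glia gate 41.1% ± 14.7 of nuclei were labelled oligodendrocytes against 21.9% ± 13.9 in CK (exact permutation p = 0.0346, adjusted p = 0.143).

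**Figure D2:**
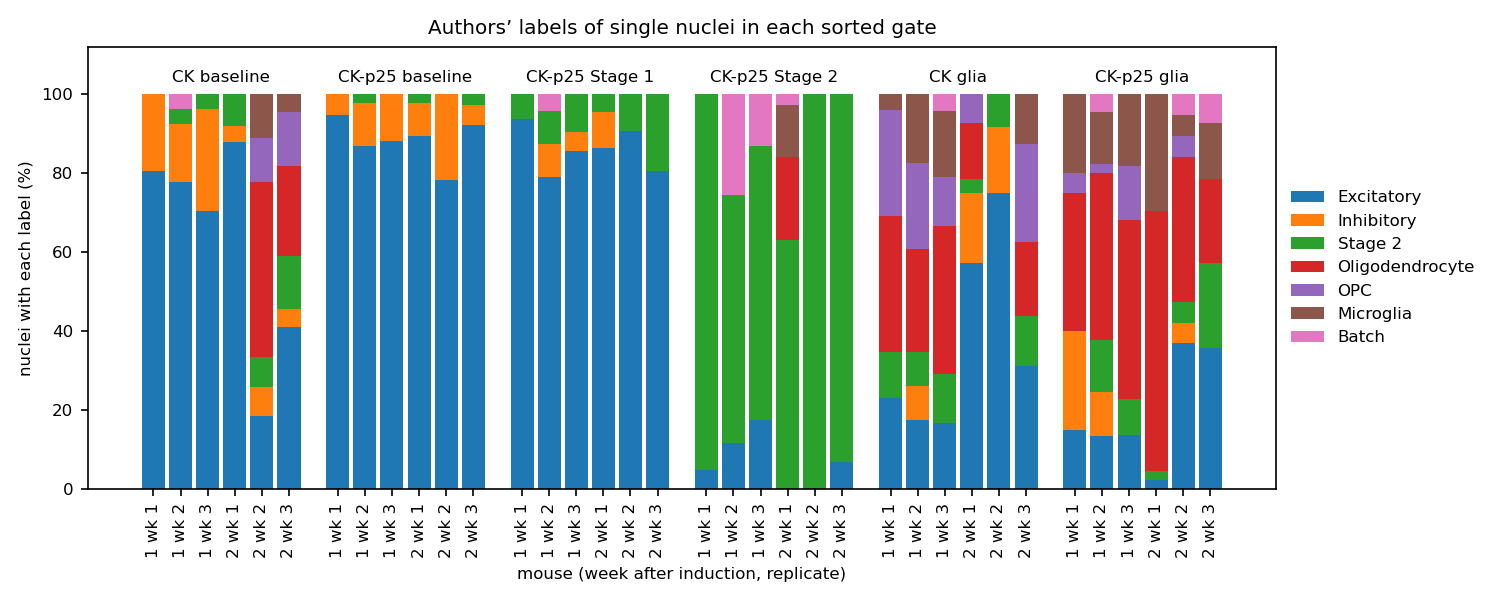
Share of nuclei (percent) with each of the authors' labels, as stacked bars for each mouse and gate. Stage 2 nuclei of CK-p25 mice mostly carried the label Stage 2, and the baseline gate of CK mouse 2 at 2 weeks held 25.9% neuronal labels.

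Counts of single nuclei were summed per mouse and gate. Each CK-p25 mouse was sequenced in its own run and the CK mice of each week in 1 run, so genotype and run cannot be told apart in comparisons between genotypes. Stage 1 sums carried higher RNA of cell cycle and p53 genes than CK baseline sums (n = 6 mice each). Pidd1 was at least 164-fold higher, with 834 counts against 0, the DNA polymerase gene Pole at least 88.4-fold, the kinetochore gene Kntc1 at least 81.0-fold and the topoisomerase Top2a at least 68.6-fold. These bounds rest on a floor of 3 counts over the group and cover counting error only. Cdkn1a, the cell cycle inhibitor p21, rose by 5.65 ± 0.91, from 4.81 to 235 CPM. Of 15 cell cycle genes, 9 rose and 0 fell (15 adjusted over the list alone), among them Mcm2, at least 34.0-fold higher. Of 18 p53 targets, 4 rose and 0 fell (5 adjusted over the list alone), among them Phlda3, at least 19.8-fold higher. The genes that fell included Apoe at -2.99 ± 0.76, the amyloid precursor-like gene Aplp1 at -2.37 ± 0.61, the cyclase Adcy5 at -3.21 ± 0.76 and the cargo receptor Surf4 at -3.41 ± 0.86. The direction of Apoe turned to 0.57 without the CK 2 week mice and to 0.77 at 1 week alone, and against the CK-p25 baseline gate of the same mice Apoe turned to 0.86 and Surf4 to 0.32. EdgeR called 94 genes higher and 16 lower. In nuclei labelled excitatory 107 genes were called, of which 44 were among the 110, and Aplp1, Apoe and Surf4 lost their call, at -1.15, -0.02 and -1.07. The count of 110 was 16 without the CK 2 week mice, 12 at 1 week and 7 at 2 weeks. Leaving out CK-p25 mouse 1 or 3 at 1 week or mouse 3 at 2 weeks gave 61, 59 and 63, and the CK-p25 baseline gate as reference gave 31.

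Stage 2 sums differed from CK baseline in more genes, 403 higher and 542 lower by edgeR. Cdkn1a rose by 7.78 ± 0.96, from 4.81 to 1076 CPM, and Mki67 by 7.35 ± 0.90, from 5.86 to 1068 CPM. Pidd1 was at least 175-fold higher, Ckap2, a spindle protein, at least 194-fold, Gtse1, a regulator of p53, at least 185-fold and Top2a at least 42.7-fold. Of 17 ribosomal protein genes, 2 rose and 0 fell (7 adjusted over the list alone), and of 7 mitochondrially encoded RNAs 0 passed by edgeR (4 adjusted over the list alone, 4 at an unadjusted p under 0.05, 1 higher by DESeq2), with medians of 1.02 and 1.38 (camera adjusted p = 0.0145 and 0.287 with an estimated correlation). All 15 cell cycle genes measured and 10 of 18 p53 targets rose, and 0 fell (15 and 11 adjusted over each list alone). Cdk5r1 (or p25) rose by 4.40 ± 0.88, from 17.4 to 366 CPM, and B2m by 3.01 ± 1.01. The list of 12 immediate early genes was not called (3 rose and 0 fell, 3 adjusted over the list alone, camera adjusted p = 0.15 with a preset correlation), with Egr1 at 2.82 ± 0.66 and Btg2 at 3.67 ± 1.01. Synapse genes fell in 8 of 32 cases and rose in 0 (17 adjusted over the list alone), with the glutamate receptor Gria2 at -2.51 ± 0.49, Cntnap2 at -3.26 ± 0.67, Nrxn3 at -2.34 ± 0.46 and the calcium channel Cacna1e at -2.54 ± 0.58 (camera adjusted p = 0.16 with an estimated correlation). Gfap rose by 4.47 ± 1.5. The count of 945 was 485 without the CK 2 week mice, 323 at 1 week and 166 at 2 weeks.

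Between the gates of the same CK-p25 mice, with the mouse as a block, Stage 2 had higher Bex3 (3.96 ± 0.61, from 95.4 to 1450.5 CPM), Apoe (2.57 ± 0.49), the metallothionein Mt1 (3.96 ± 0.76), the p53-responsive kinase Plk2 (2.89 ± 0.63) and Cdkn1a (2.32 ± 0.64). Mitochondrially encoded RNAs rose in 4 of 7 cases and fell in 0 (6 adjusted over the list alone), with mt-Cytb at 2.00 ± 0.41 and mt-Nd5 at 2.13 ± 0.49 (camera adjusted p = 0.15 with an estimated correlation). Synapse genes fell in 6 of 32 cases and rose in 0 (11 adjusted over the list alone), with Cacna1e at -3.10 ± 0.72, Cntnap2 at -3.51 ± 0.95 and Nrxn3 at -2.45 ± 0.60 (camera adjusted p = 0.29 with an estimated correlation). EdgeR called 80 genes higher and 94 lower around a median of -0.72 over all genes, and relative log expression scaling, which moved that median by -0.11, gave 84 higher and 160 lower. The count of 174 was 75 at 1 week and 9 at 2 weeks, and 77, 104, 65 and 97 without mouse 1 or 2 at 1 week or mouse 1 or 2 at 2 weeks.

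The baseline sums of CK-p25 and CK mice differed in 18 genes by edgeR, 3 higher and 15 lower. Pole was at least 27.1-fold and Kntc1 at least 13.2-fold higher, and Zgrf1, a helicase-related gene, rose by 3.75 ± 0.87. The genes that fell included the iron store gene Fth1 at -3.75 ± 0.56, the protease inhibitor Cst3 at -3.28 ± 0.64, Apoe at -4.16 ± 0.76, Mbp at -4.26 ± 0.85 and Aldoc at -5.20 ± 1.03. Oligodendrocyte markers had 1 of 6 lower and 0 higher (5 adjusted over the list alone; camera adjusted p = 0.071 with an estimated correlation). Among 7 astrocyte markers 1 was lower and 0 higher (5 adjusted over the list alone; camera adjusted p = 0.0502 with an estimated correlation). Without the CK 2 week mice edgeR called 0 genes (490 at an unadjusted p under 0.05), 1 week alone gave 0 and 2 weeks alone 10, and in nuclei labelled excitatory 13 genes were higher and 1 lower. Of these 14, 3 were among the 18, and Fth1, Cst3, Apoe, Mbp and Aldoc lost their call, at -1.3, -0.66, -0.76, -1.54 and -1.02. In the glia sums edgeR called 0 genes, with 152 at an unadjusted p under 0.05 and 1 call by DESeq2. In simulated data of that comparison edgeR recovered 81.0% of genes changed 32-fold and 6.82% of those changed 4-fold.

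Etoposide changed most expressed genes of cultured neurons, raising p53, interferon and NF-kB genes and lowering synaptic, excitatory and precursor genes (n = 3 libraries each). Gdf15, a stress cytokine, rose by 3.73 ± 0.16, Pmaip1 by 3.40 ± 0.05, the death receptor Tnfrsf10b by 2.67 ± 0.10, Phlda3 by 2.09 ± 0.05 and Cdkn1a by 1.88 ± 0.04, from 67.3 to 248 CPM. Of 30 p53 targets, 25 rose and 4 fell (29 adjusted over the list alone). Interferon genes rose in 24 of 31 cases and fell in 1 (25 adjusted over the list alone), with the exonuclease Isg20 at 5.36 ± 0.13, the regulator Irf7 at 4.20 ± 0.25 and Usp18 at 3.50 ± 0.23. NF-kB targets and cytokines rose in 23 of 32 cases and fell in 3 (26 adjusted over the list alone), with the adhesion gene Icam1 at 3.44 ± 0.13, the cytokine Lif at 2.82 ± 0.16, Ccl2 at 2.42 ± 0.38 and Cxcl10 at 2.26 ± 0.20. Rela rose by 0.98 ± 0.05. Each of these 3 lists had a camera adjusted p = 0.17 with an estimated correlation. Antigen presentation genes rose in 16 of 20 cases and fell in 0 (16 adjusted over the list alone), with the proteasome gene Psmb8 at 2.90 ± 0.26 and Tap1 at 2.58 ± 0.07 (camera adjusted p = 0.33 with an estimated correlation). Markers of myeloid cells moved as well. Spi1 rose by 5.53 ± 0.43, from 0.0477 to 2.31 CPM, and the receptor Csf1r by 2.86 ± 0.27, in a homeostatic microglia list with 6 of 13 genes higher and 2 lower (8 adjusted over the list alone). Itgax rose by 3.42 ± 0.80, to 0.282 CPM, and the lysosomal gene Cd68 by 2.20 ± 0.14, from 1.41 to 6.46 CPM, in a disease associated list with 11 of 20 higher and 4 lower (15 adjusted over the list alone). Neither list was called by camera (adjusted p = 0.257 and 0.0641 with a preset correlation).

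Synapse genes fell in 27 of 31 cases and rose in 3 with etoposide (30 adjusted over the list alone; camera adjusted p = 0.33 with an estimated correlation). The glutamate receptor genes Grin2a and Grin2b fell by 3.02 ± 0.05 and 2.89 ± 0.07, the calcium channel Cacna1c by 2.65 ± 0.05 and the adhesion gene Nlgn1 by 2.67 ± 0.04. Excitatory markers fell in 10 of 12 cases and rose in 0 (10 adjusted over the list alone; camera adjusted p = 0.17 with an estimated correlation), including the cortical transcription factors Rorb (-2.65 ± 0.06) and Tbr1 (-2.53 ± 0.06). Oligodendrocyte precursor markers fell in 10 of 10 (10 adjusted over the list alone; camera adjusted p = 0.33 with an estimated correlation), with Sox10 at -4.99 ± 0.23, Pdgfra at -4.86 ± 0.16 and Olig2 at -2.89 ± 0.06. Cell cycle genes fell in 19 of 25 cases and rose in 3 (23 adjusted over the list alone), with Top2a at -3.19 ± 0.08 and Mki67 at -2.71 ± 0.07 (camera adjusted p = 0.38 with an estimated correlation). Repair genes fell in 22 of 32 cases and rose in 5 (27 adjusted over the list alone), with Parp1 at -1.42 ± 0.04 and Trp53bp1 at -1.50 ± 0.04 (camera adjusted p = 0.33 with an estimated correlation). Cdk5r1 fell by 1.34 ± 0.04 and Rbfox3 by 1.06 ± 0.03. EdgeR called 7413 genes higher and 7344 lower.

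Genes changed by etoposide overlapped those of the Stage 1 gate, which shares no library with the culture. Among 15974 genes tested in both, 1781 were higher in both against 1128 for independent lists (Fisher's exact odds ratio 2.82, 95% interval 2.61 to 3.05), and 1986 were lower in both against 1197 (odds ratio 4.07, interval 3.72 to 4.44). Others were called in opposite directions, 415 higher with etoposide and lower in Stage 1, and 898 lower with etoposide and higher in Stage 1. Across genes, which are not independent replicates, fold changes had a Spearman rho of 0.379. The overlap was not tested apart from genomic span or abundance of the genes. Higher in both were 20 of 29 p53 targets, 17 of 31 interferon genes, 9 of 17 immediate early genes and 8 of 18 antigen presentation genes, beside 4 of 13 homeostatic and 6 of 19 disease associated microglia genes. Of 31 synapse genes 21 were lower in both. The cell cycle and repair lists went opposite ways, higher in Stage 1 and lower with etoposide or the reverse, for 18 of 25 and 15 of 31 genes.

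**Figure D3:**
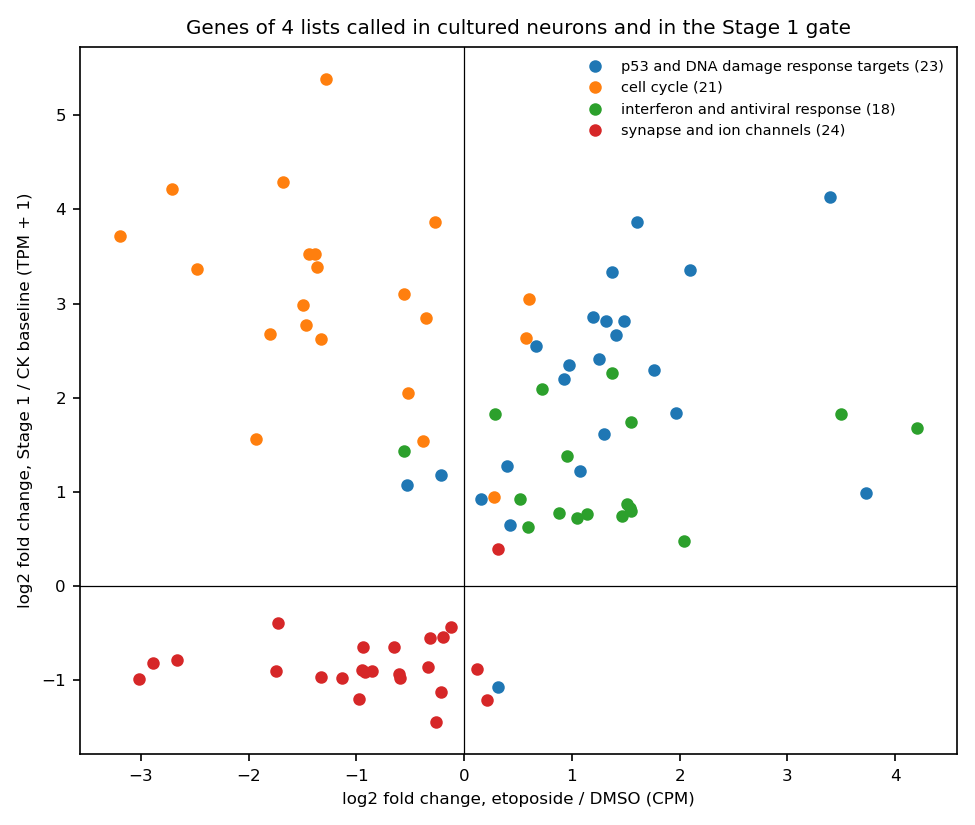
Log2 fold change of etoposide over DMSO (x axis) and of Stage 1 over CK baseline (y axis) for members of 4 lists that were called in both comparisons. Points are genes. Most p53 and interferon genes lie in the upper right, synapse genes in the lower left, and 18 cell cycle genes on opposite sides of 0.

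Rela, the target of the knockdown, was measured first in the PU.1-sorted libraries. It stood at 29.7 CPM in the libraries labelled p65 knockdown, 29.1 CPM in the scramble libraries and 23.7 CPM in the PBS libraries. The difference of the libraries labelled p65 knockdown from scramble was 0.03 ± 0.12 (edgeR, adjusted p = 0.95), so RNA of the target did not go with the label. This is RNA of PU.1-sorted nuclei, so it does not test a knockdown of the protein or in other cells. Directions below are those of the libraries labelled p65 knockdown.

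Microglial nuclei of CK-p25 scramble mice had higher interferon, disease-associated and proliferation RNA than those of CK PBS mice (n = 3 libraries each). These groups differ both in genotype and in what the mice were given, so effects of genotype and of the scrambled control cannot be told apart. Cxcl10 rose by 5.71 ± 0.49, from 0.248 to 13.7 CPM, the antiviral enzyme Oas2 by 5.33 ± 0.23, from 3.77 to 151 CPM, and the nucleic acid sensor Zbp1 by 5.16 ± 0.25. All 35 interferon genes rose (35 adjusted over the list alone; camera adjusted p = 0.06 with an estimated correlation). Genes of disease associated microglia rose in 22 of 24 cases and fell in 0 (23 adjusted over the list alone). They included Clec7a, a pattern receptor, at 4.99 ± 0.21, the integrin Itgax at 4.96 ± 0.22, Cst7 at 4.42 ± 0.44, the receptor Axl at 4.26 ± 0.21, Apoe at 1.66 ± 0.14 and Trem2 at 0.89 ± 0.15. Cell cycle genes rose in 23 of 25 cases and fell in 0 (24 adjusted over the list alone), with Mki67 at 3.63 ± 0.24 and Cenpe at 3.32 ± 0.18.

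Antigen presentation genes rose in 18 of 20 cases and fell in 0 (19 adjusted over the list alone), with Nlrc5 at 4.15 ± 0.17 and H2-Q7 at 3.87 ± 0.22 (camera adjusted p = 0.12 with an estimated correlation). NF-kB targets and cytokines rose in 25 of 33 cases and fell in 3 (29 adjusted over the list alone), with Ccl2 at 4.43 ± 0.36 and Ccl3 at 3.85 ± 0.27 (camera adjusted p = 0.063 with an estimated correlation). Phagocytosis and lysosome genes rose in 22 of 25 cases and fell in 0 (22 adjusted over the list alone), with the protease Ctsd at 1.61 ± 0.17 (camera adjusted p = 0.18 with an estimated correlation). Homeostatic microglia genes were split, 5 of 20 higher and 5 lower (12 adjusted over the list alone), with the purinergic receptor P2ry12 at -0.73 ± 0.12, C1qa at 0.70 ± 0.16 and C1qb at 0.79 ± 0.14. Markers of other cells were abundant and moved as well. The mean log2(CPM + 1) of the synapse list was 7.43 to 7.54 in PBS and 6.57 to 6.96 in scramble libraries, beside 6.96 to 7.41 and 7.21 to 7.42 for the homeostatic microglia list. Synapse genes fell in 30 of 32 cases and rose in 0 (30 adjusted over the list alone), with Grin1 at -1.02 ± 0.14 and Homer1 at -1.09 ± 0.19 (camera adjusted p = 0.18 with an estimated correlation). The activity gene Arc fell by 2.12 ± 0.28 and Gfap rose by 2.08 ± 0.23. EdgeR called 2759 genes higher and 2576 lower.

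Libraries labelled p65 knockdown differed from scramble libraries in 6 genes by edgeR, 1 higher and 5 lower, with 3782 at an unadjusted p under 0.05. Apoe fell by 1.14 ± 0.13, from 346 to 157 CPM (edgeR, adjusted p = 0.023). Of 24 genes of disease associated microglia, 1 fell and 0 rose (14 adjusted over the list alone; camera adjusted p = 0.082 with an estimated correlation), and Cd74, the invariant chain, stood at -1.21 ± 0.23 without passing. In the phagocytosis and lysosome list 0 of 25 genes passed by edgeR (15 adjusted over the list alone, 15 at an unadjusted p under 0.05, 4 lower by DESeq2; camera adjusted p = 0.18 with an estimated correlation), with Ctsd at -0.74 ± 0.17 and Ctss at -0.74 ± 0.18. No interferon gene passed (0 of 35, 6 adjusted over the list alone, 11 unadjusted, 4 lower by DESeq2; camera adjusted p = 0.25 with an estimated correlation), nor did an NF-kB target (0 of 33, 0 adjusted over the list alone, 7 unadjusted, 0 by DESeq2; camera adjusted p = 0.26 with an estimated correlation). Cxcl10 differed by 0.14 ± 0.31. Antigen presentation genes (0 of 20, 10 adjusted over the list alone, 11 unadjusted, 8 lower by DESeq2) had a median of -0.42, and complement genes (0 of 18, 9 adjusted over the list alone, 10 unadjusted, 6 lower by DESeq2) one of -0.47 (camera adjusted p = 0.182 and 0.134 with an estimated correlation). Mitochondrially encoded RNAs (0 of 12, 8 adjusted over the list alone, 9 unadjusted, 3 lower by DESeq2) had a median of -0.73 (camera adjusted p = 0.224 with an estimated correlation). Homeostatic microglia genes (0 of 20, 3 adjusted over the list alone, 7 unadjusted, 3 lower by DESeq2) had a median of -0.30. Synapse genes (0 of 32, 18 adjusted over the list alone, 19 unadjusted, 13 higher by DESeq2) had a median of 0.43. In the estimated-correlation test the homeostatic and synapse lists had camera adjusted p = 0.28 and 0.21.

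The other calls, named after their values were seen, were Pla2g4e at 1.40, Tnfsf8 at -1.40, H2-Q1, H2-Q2 and Gm28439, the H2-Q genes being near copies that counting cannot separate safely. The count of 6 was 672 without the library labelled knockdown replicate 1, 0 without that labelled knockdown replicate 3, and 13, 2 and 2 without scramble replicate 1, 2 or 3. It was 787 by DESeq2, 18 with the 6 libraries alone, 20 without PBS replicate 1 and scramble replicate 1, which detected more genes than the rest, and 1247 with no filter on low counts. Relative log expression scaling gave 3 higher and 5 lower.

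Of the 5335 genes called between scramble and PBS, 85.4% differed in the opposite direction between the libraries labelled knockdown and scramble. Both comparisons use the scramble libraries, and simulated unchanged libraries in their place gave 61.2% (59.7 to 62.6 over 100 simulations). The covariance of the fold changes was -0.423 against -0.154 in the simulations. Of the 20 assignments of CK-p25 libraries to labels, 3 gave a share at least as high, the real one included. The lowest and highest other were 31% and 88.0% (median 60.8%), so simulations understate the spread. The libraries labelled p65 knockdown differed from PBS libraries, with 1588 genes higher and 699 lower by edgeR. Here too genotype and what the mice were given cannot be told apart. Oas2 rose by 4.43 ± 0.23, Zbp1 by 4.51 ± 0.25, Cxcl10 by 5.85 ± 0.49, Itgax by 4.13 ± 0.22, Clec7a by 4.05 ± 0.22 and Axl by 3.67 ± 0.21. All 35 interferon genes, 23 of 25 cell cycle genes and 17 of 24 disease associated genes (0 lower) rose (35, 24 and 21 adjusted over each list alone). Oligodendrocyte markers fell in 9 of 12 cases (12 adjusted over the list alone), with Mal at -1.37 ± 0.23, and synapse genes in 5 of 32 (7 adjusted over the list alone), with Snap25 at -0.73 ± 0.15. These 2 lists had camera adjusted p = 0.13 and 0.28 with an estimated correlation. The count of 2287 was 1459 and 1280 without PBS replicate 2 or 3, and 1273 and 1130 without the library labelled knockdown replicate 1 or 2.

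**Figure D4:**
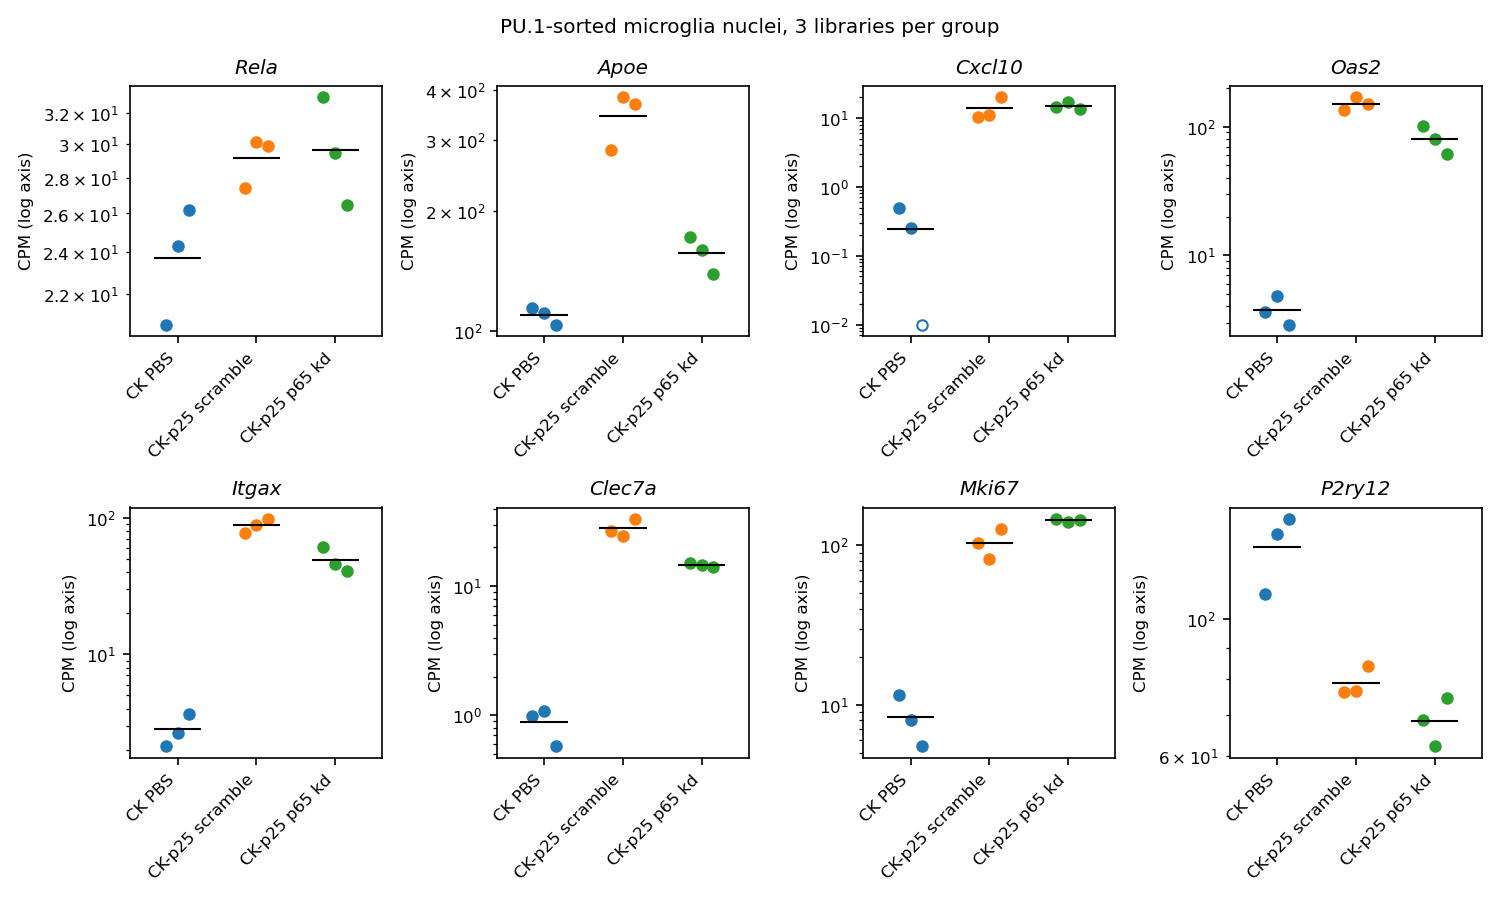
CPM (log axis) of 8 genes in the 9 PU.1-sorted libraries. Points are libraries, lines are group means, and an open point marks a library with 0 counts. Rela did not separate libraries labelled knockdown from scramble (29.7 and 29.1 CPM), while Apoe was 157 CPM in libraries labelled knockdown and 346 CPM in scramble.

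Whole brain sections of CK-p25 mice had higher interferon, microglial, proliferation and astrocyte RNA than CK sections (n = 4 and 3). Cxcl10 rose by 6.81 ± 0.61, from 0.299 to 34.4 CPM, Isg15 by 4.62 ± 0.54, Ifi27l2a by 4.21 ± 0.30 and Irf7 by 4.10 ± 0.27. Cst7 rose by 6.12 ± 0.28, from 0.333 to 23.1 CPM, Itgax by 3.78 ± 0.35 and Trem2 by 1.44 ± 0.13. The mitotic kinase Cdk1 rose by 5.20 ± 0.26, Mki67 by 4.43 ± 0.57 and Top2a by 4.11 ± 0.40. Oxt and Avp, neuropeptides of the hypothalamus, fell by 6.92 ± 1.05 and 6.36 ± 0.85, and Trh by 2.02 ± 0.25. EdgeR called 798 genes higher and 60 lower.

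By list, 33 of 33 interferon genes rose (33 adjusted over the list alone; camera adjusted p = 0.054 with an estimated correlation), as did 23 of 25 cell cycle genes with 0 lower (23 adjusted over the list alone; adjusted p = 0.068 with an estimated correlation). Homeostatic microglia genes rose in 13 of 20 cases and fell in 0 (16 adjusted over the list alone; adjusted p = 0.068 with an estimated correlation), with C1qb at 1.64 ± 0.14 and Spi1 at 1.58 ± 0.19. Phagocytosis and lysosome genes rose in 15 of 25 and fell in 0 (19 adjusted over the list alone), with Cd68 at 1.7 ± 0.22. Disease associated microglia genes rose in 14 of 23 and fell in 0 (16 adjusted over the list alone; adjusted p = 0.0504 with an estimated correlation). NF-kB targets and cytokines rose in 8 of 32 and fell in 0 (17 adjusted over the list alone; adjusted p = 0.0503 with an estimated correlation), with the chemokine Ccl5 at 4.42 ± 0.61, and outside the lists the chemokine Ccl12 rose by 5.02 ± 0.42. Reactive astrocyte genes rose in 7 of 17 and fell in 0 (14 adjusted over the list alone; adjusted p = 0.061 with an estimated correlation), with Gfap at 2.12 ± 0.27, Serpina3n at 2.07 ± 0.15 and Timp1 at 3.11 ± 0.23, and complement gene C4b rose by 2.15 ± 0.25. All of these adjusted p are from camera.

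Antigen presentation genes rose in 12 of 19 cases and fell in 0 (17 adjusted over the list alone; camera adjusted p = 0.061 with an estimated correlation), with H2-Q7 at 3.14 ± 0.27 and Psmb8 at 2.27 ± 0.18. Of 30 p53 targets, 7 rose and 0 fell (11 adjusted over the list alone; camera adjusted p = 0.13 with an estimated correlation), with Pidd1 at 3.08 ± 0.44, Pmaip1 at 2.06 ± 0.22 and Cdkn1a at 1.34 ± 0.25. Of 19 immediate early genes, 4 fell and 0 rose (7 adjusted over the list alone; camera adjusted p = 0.18 with an estimated correlation), with Arc at -1.34 ± 0.26, Nr4a1 at -0.96 ± 0.18 and Egr1 at -0.61 ± 0.12. Lipid and cholesterol genes fell in 6 of 21 cases and rose in 0 (11 adjusted over the list alone; camera adjusted p = 0.45 with an estimated correlation), with the synthesis enzymes Hmgcs1 at -0.60 ± 0.08 and Sqle at -0.59 ± 0.09. Same-numbered sections deviated together beyond genotype, but for CK sections 1 and 2 a CK-p25 section of another number did so more. With the replicate number as a block edgeR called 1024 genes higher and 302 lower. With the 2 slides as a covariate these were 1221 and 443. The count of 858 was 481 and 522 without CK replicate 1 or 2.

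**Figure D5:**
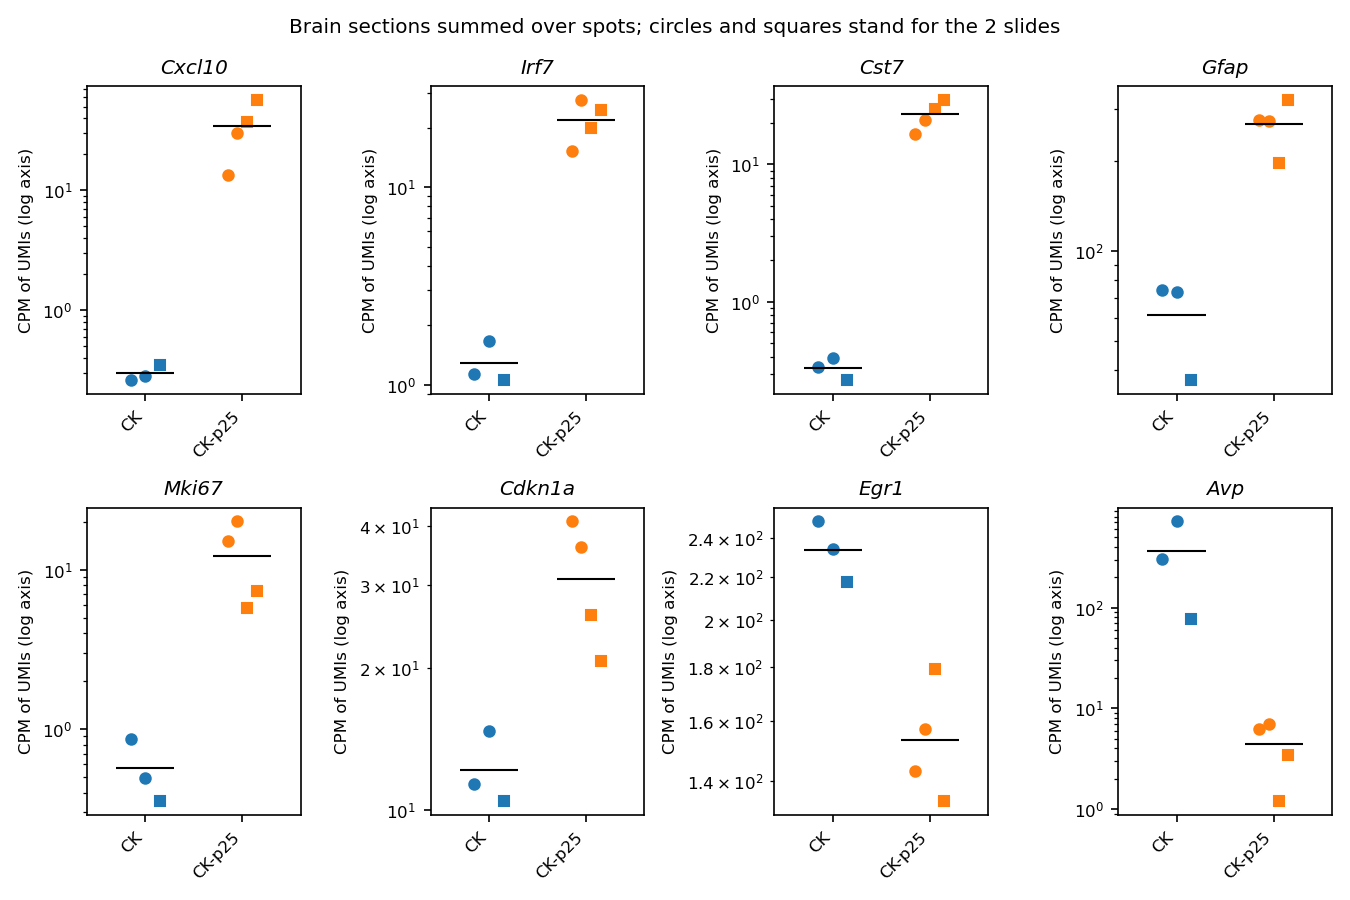
CPM of UMIs (log axis) of 8 genes in 3 CK and 4 CK-p25 sections, summed over all spots. Points are sections, shapes are the 2 slides and lines are means. Cxcl10 was 34.4 CPM in CK-p25 and 0.299 CPM in CK, and Avp was 4.46 and 365 CPM, with 76.6 to 716 CPM among the CK sections.

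The authors' spot clusters served as regions. The 18 with enough spots for a test varied in number of calls. Region 6, led in CK by Ccn3 and C1ql3, had 566 genes higher and 107 lower. Region 7, led by Lamp5 and Vip, had 453 and 74, region 9, led by Cabp7 and Camk2a, 324 and 101, region 16, led by Spink8 and Neurod6, 345 and 51, and region 5, led by Trbc2 and Myl4, 330 and 27. The striatal region 2, led by Penk and Pde10a, had 248 and 12. Fewer were called in other regions with cortical genes in the lead, 151 and 27 in region 12, led by Egr1 and Lamp5, 148 and 8 in region 4, led by Myl4 and Lamp5, and 82 and 2 in region 14, led by Ccn2 and Cplx3. Region 3, led by Tcf7l2 and Prkcd, had 3 calls and region 17, led by the choroid plexus gene Ttr, 2. Ifi27l2a rose in 15 of 18 regions, Ifitm3 in 13 and the microglial gene C1qb in 12. Gfap rose by 3.43 ± 0.48 in region 6 and 3.33 ± 0.33 in region 7. Summed over regions, edgeR called 2949 genes higher and 423 lower, 4771 and 2451 with the replicate block, and 4727 and 1950 with the slide as a covariate. The total of 3372 was 1819 and 1957 without CK replicate 1 or 2, 2246 and 2053 without CK-p25 replicate 2 or 4, and 6318 with no filter on low counts.

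The relation of damage and microglia was measured across spots as the correlation of the UMI shares of the p53 list and the disease associated microglia list, after regression on total UMIs and region. Mean rho was 0.0074 ± 0.0118 in CK-p25 sections (SD, n = 4) and -0.0202 ± 0.0202 in CK sections (n = 3). The difference of 0.0276 had p = 0.0857 in a two-sided exact permutation test, where the smallest possible p is 0.0286. Between sections of the same number, which are not shown to be pairs, the difference was 0.0235, 0.0194 and 0.0347, higher in CK-p25 in 3 of 3. With the numbers taken as pairs the exact permutation p was 0.25, the smallest that 3 pairs allow. Within the slides it was 0.0214 (2 CK-p25 and 2 CK sections) and 0.0451 (2 and 1). The lists themselves took larger shares in CK-p25. P53 targets made up 0.0642% to 0.0829% of UMIs against 0.0577% to 0.0626% in CK, and disease associated microglia genes 0.472% to 0.527% against 0.317% to 0.394%.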

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

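The tests of microglial RNA and background reads in Stage 1, of division genes and of all 25 cell cycle genes in nuclei labelled excitatory, of exchanged gates, of the microglia share in the libraries labelled knockdown and of section splits within slides were chosen only after the result was seen.

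Cell cycle genes were higher in the Stage 1 gate, in bulk and in single nuclei. Nuclei labelled excitatory argue against sorted proliferating glia as the whole source. Their median log2 ratio to CK baseline over all 25 genes, without a filter, was 3.12 (95% bootstrap interval over genes, not mice, 2.71 to 4.12). Genes under 3 counts in CK were set to 3 over the group. In these nuclei RNA of 11 division genes, among them Mki67, Top2a and Cdk1, stood at 118 to 1065 CPM in Stage 1 and 5.18 to 58.2 CPM in the baseline gate of the same mice and runs (higher in 6 of 6 mice, median log2 ratio 5.64, range 1.24 to 6.47), with Cdc20 alone of the 11 lower, at -2.21. The same nuclei had lower excitatory markers than that baseline gate (1107 against 1631 CPM, higher in 0 of 6 mice), while oligodendrocyte markers stood at 468 against 378 CPM (higher in 5 of 6), homeostatic microglia markers at 295 against 111 CPM (2 of 6) and astrocyte markers at 858 against 957 CPM (2 of 6), so glial RNA within them stays open. In bulk, medians were 0.263 (0.031 to 0.562 over genes) for homeostatic microglia and 0.0119 for 1008 olfactory receptor genes, far below 2.99 for cell cycle genes. This argues against homeostatic microglia and background reads as the whole source. A hypothesis is that damaged neurons switch on replication or division genes. Wrong labels, activated microglia (not tested), other glia beside the neurons and effects of the sort stay open, and genotype and run cannot be told apart against CK.

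CK gates at 2 weeks held mixed nuclei. An exchange of the baseline and glia gates in mouse 2 is a candidate explanation, with 25.9% neuronal labels in its baseline gate and 91.7% in its glia gate (95% intervals 11.1 to 46.3 and 73.0 to 99.0). An exchange within mouse 1 is argued against by 92.0% neuronal labels in its baseline gate (74.0 to 99.0). Its glia gate held 75.0% (55.1 to 89.3) against 16.7% to 26.1% at 1 week, a high share that an exchange would give. An exchange with a gate of another mouse was not tested. Within mouse 3 it is argued against by 31.25% in the glia gate (11.0 to 58.7), below the 92.6% or more of 1 week baseline gates, but its baseline gate held only 45.5% (24.4 to 67.8), so mixed nuclei in mice 1 and 3 stay unexplained. Low depth in that run is argued against by a ratio of 0.927 (0.835 to 1.01) to the 1 week run in median counts per nucleus, and no biological explanation was tested.

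Genes of disease associated microglia had a median log2 difference of -0.478 between the libraries labelled p65 knockdown and scramble libraries, while Rela differed by 0.03 ± 0.12. EdgeR called 1 of the 24 genes, and the list had a camera adjusted p = 0.082 with an estimated correlation. A lower share of microglia may account for it, with a homeostatic median of -0.301 and a synapse median of 0.427. The gap of the disease associated below the homeostatic list mean was -2.08 ± 0.10 and -1.90 ± 0.07 per library (SD, n = 3 each, difference -0.18, no overlap). The exact two-sided permutation p of 0.1 is the smallest for 3 against 3, so it cannot separate this share from a change in microglia. The library labelled knockdown replicate 3 alone is argued against by a median of -0.418 without it, while an effect of the treatment, RNA quality, with a mitochondrially encoded median of -0.73, and any difference between these mice stay open.

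A sample far from the rest of its group appeared in 9 of 138 groups tested (6.52%), where chance gives about 1 in 20. The values are gaps to the nearest sample as a share of the range. In Stage 1 single nuclei Adcy5 was lowest in CK-p25 mouse 1 at 1 week (0.656), and the Stage 2 label was most frequent in mouse 3 at 2 weeks (0.664). In Stage 2 nuclei Mki67 was lowest in mouse 1 at 2 weeks (0.835) and Gfap lowest in mouse 3 at 2 weeks (0.631), and microglia and oligodendrocyte labels occurred in mouse 1 at 2 weeks alone (1 each). In CK baseline nuclei Gfap was found in mouse 3 at 1 week alone (1). Among CK-p25 sections Timp1 was highest in section 4 (0.851) and Nr4a1 in section 3 (0.945).

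The Stage 1 difference from CK baseline in single nuclei itself differed between 1 and 2 weeks in 1 gene, Apoe, by -5.41 (edgeR interaction, adjusted p = 0.0095). The Stage 2 difference did so in 29 genes, among them Apoe by -5.14 and the glutamate transporter Slc1a2 by -4.42. The CK baseline gates of mice 2 and 3 at 2 weeks held 25.9% and 45.5% neuronal labels, and those of the 3 CK mice at 1 week 92.6% to 100.0%. EdgeR found 0 such genes for baseline, glia and Stage 2 against Stage 1, with 803, 496 and 1386 at an unadjusted p under 0.05, and DESeq2 was not run for it. The authors' flag for p25, which no comparison used, was set in 49.2% of 708 CK-p25 nuclei and in 17.0% of 300 CK nuclei.

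Other splits of the same samples were counted for each comparison with at least 3 samples per group, real split included. In single nuclei 1 of 100 drawn splits gave as many genes for Stage 1 (110, highest other 1), Stage 2 (945, highest other 79) and baseline (18, highest other 7). Chance is argued against there only for mice taken as exchangeable. These splits ignore that the CK mice of each week share 1 run while each CK-p25 mouse has its own. The baseline count also fell to 0 without the CK 2 week mice and to 3 without CK-p25 mouse 3 at 1 week. For Stage 2 against Stage 1, exchanged within mice, 1 of 32 splits gave as many (174, highest other 3), so chance can be excluded. For glia the count was 0, which all 100 of 100 splits reach by construction, so they test nothing. The 10 splits of etoposide (14757, highest other 0), scramble against PBS (5335, highest other 1), libraries labelled knockdown against scramble (6, highest other 1) and against PBS (2287, highest other 1) are too few for a share under 0.05, with 1 split as large in each. So are the 8 for marked spots (977, highest other 1) and for neighbouring spots (289, highest other 14). For sections 2 of 35 splits gave as many genes as 858 in the whole section (highest other 2572) and as 3372 over regions (highest other 12066), so chance cannot be excluded by this count, which ignores slides and pairs. The larger split is that of the 2 slides, which points to a structure of the samples. With the slide as a covariate 1664 and 6677 genes were called. The other 17 splits within slides gave at most 0 and 1539, and 18 splits are too few for a share under 0.05, with 1 as large in each. Among the 8 splits that part every pair of same-numbered sections, also too few, the real one gave 858 and 3372 and the highest other 0, while the remaining splits keep at least 1 pair on one side.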

How the results depend on the processing

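The fits of TPM without scaling or with a pseudocount of 0.1, without the CK 2 week mice, in nuclei labelled excitatory or without nuclei labelled Batch, with the CK-p25 baseline as single-nucleus reference, without the libraries with most genes, with crossed numbers, of the reversal share with a block, of the spot relation in pairs or in unmarked spots, and all those of marked and neighbouring spots were chosen only after seeing the data.

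Over 23 results, 98 of 144 alternative values kept their side of the threshold or stayed within 1.5 times the count, and 88 of 130 values with 1 replicate left out did. For the 275 named values, 3228 of 3562 alternatives (90.6%) kept direction and call, 315 lost the call, 10 gained it and 9 reversed. The cause was not tested unless stated. With DESeq2 the count was 339 for single-nucleus Stage 1, 2404 for Stage 2, 134 for baseline, 1 for glia and 1918 for Stage 2 against Stage 1, 787 for libraries labelled knockdown against scramble, 1362 for whole sections, 208 for marked spots and 55 for neighbouring spots. DESeq2 was not run on the bulk gates, which hold TPM. With no low count filter it was 283, 107, 8 and 73 for single-nucleus Stage 1, baseline, glia and Stage 2 against Stage 1, 1247 for libraries labelled knockdown against scramble and 6318 over regions. Bulk baseline gave 65 without scaling and 176 with a pseudocount of 0.1. At 2 weeks alone single-nucleus Stage 1, Stage 2, baseline and Stage 2 against Stage 1 gave 7, 166, 10 and 9, and at 1 week alone 12, 323, 0 and 75, with fewer mice. Without the CK 2 week mice the first 3 gave 16, 485 and 0 (edgeR, 490 unadjusted). With all nuclei baseline gave 6 and Stage 2 against Stage 1 gave 108. With the CK-p25 baseline as reference and a replicate block Stage 1 gave 31. Libraries labelled knockdown against scramble gave 18 in a fit of the 6 libraries and 20 without the libraries with most genes. The slide as a covariate gave 1664 for whole sections and 6677 over regions. All unmarked spots as reference gave 5917 for marked spots. With an estimated correlation 95 of 878 list tests passed against 496 with the preset one, and 2292 genes overlapped at adjusted p under 0.01 against 3767.

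With the replicate number as a block, sections gave 1326 genes and regions 7222, and without the section as a block marked spots gave 1 and neighbouring spots 0. The single-nucleus block gave 92 for Stage 1, 805 for Stage 2, 10 for baseline and 0 for glia (152 unadjusted in the fit without it), and 143 for Stage 2 against Stage 1 without the mouse. Microglia gave 4757, 1 and 1968 with the block, etoposide 14542, and the reversal share was 85.7%. Bulk Stage 1, Stage 2 against Stage 1, baseline and glia gave 8016, 11820, 102 and 191 with the number as a block and 5964, 11417, 49 and 107 with the mouse. In bulk the gates of a genotype came from the same 2 mice, but no label ties a number to a mouse. In these sets the numbers were not taken as pairs, since correlations over 0.1 were found for 10 of 30 bulk, 1 of 3 etoposide, 2 of 9 microglia and 0 of 36 single-nucleus pairs. Crossing the numbers of bulk Stage 1 gave 11372 in a block fit of Stage 2 against Stage 1. The spot relation was 0.0259 over the pairs of sections and 0.0266 in unmarked spots.

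Camk2a in bulk Stage 2 against Stage 1 reversed to -0.030 without scaling. With the CK-p25 baseline as reference, with and without a replicate block, bulk Stage 1 reversed for Mx2 (-0.46) and Oasl2 (-0.45). In single-nucleus Stage 1 Apoe reversed to 0.77 at 1 week alone, 0.57 without the CK 2 week mice and 0.86 with the CK-p25 baseline as reference and a replicate block, where Surf4 gave 0.32.

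Leaving out 1 replicate gave 4444 to 6203 genes for bulk Stage 1, 11418 to 12473 for Stage 2, 8186 to 11162 for Stage 2 against Stage 1, 65 to 88 for baseline and 107 to 137 for glia, where the lone library is assumed to vary like the other groups. It gave 59 to 101 for single-nucleus Stage 1, 668 to 1110 for Stage 2, 3 to 30 for baseline, 0 for glia and 65 to 119 for Stage 2 against Stage 1. Single-nucleus baseline was 3 without CK-p25 mouse 3 at 1 week, 4 without CK-p25 mouse 1 or 2 at 2 weeks, 7 without CK mouse 2 at 2 weeks, 9 and 11 without CK-p25 mouse 2 or 1 at 1 week, 11 without CK-p25 mouse 3 at 2 weeks, 29 without CK mouse 1 at 2 weeks and 30 without CK mouse 2 at 1 week. The range was 14274 to 14755 for etoposide, 3670 to 4999 for scramble against PBS, 0 to 672 for libraries labelled knockdown against scramble and 1130 to 2107 against PBS. It was 481 to 799 for sections, 1819 to 3537 over regions, 487 to 816 for marked spots, 161 to 316 for neighbouring spots, 82.8% to 88.8% for the reversal share and 0.0163 to 0.0358 for the spot relation. At the depth and spread of the single-nucleus sums edgeR recovered 6.82% of 4-fold changes in simulated glia, and depth was not varied apart from spread.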

Other observations

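The comparisons of marked and neighbouring spots and their alternatives were chosen only after the annotation was seen.

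The authors' annotation marks spots for DNA damage in CK-p25 sections, 362, 298, 255 and 347 spots in sections 1 to 4, and none in CK sections. Marked spots had higher cell cycle and p53 RNA than unmarked spots of the same clusters. Gtse1, a regulator of p53, rose by 1.36 ± 0.13, Ckap2, a spindle protein, by 1.14 ± 0.12, Pmaip1 by 0.97 ± 0.12, Pidd1 by 0.99 ± 0.15 and Cdkn1a by 0.75 ± 0.08, from 39.5 to 66.3 CPM. Of 25 cell cycle genes 16 rose and 0 fell (20 adjusted over the list alone), and of 28 p53 targets 15 rose and 0 fell (17 adjusted over the list alone; camera adjusted p = 0.063 with an estimated correlation). Interferon genes rose in 7 of 33 cases (12 adjusted over the list alone; camera adjusted p = 0.076 with an estimated correlation), with Cxcl10 at 0.60 ± 0.08. Oligodendrocyte markers fell in 9 of 12 (11 adjusted over the list alone; camera adjusted p = 0.0504 with an estimated correlation), with Mobp at -0.46 ± 0.03. Mitochondrially encoded RNAs fell in 12 of 13 (12 adjusted over the list alone; camera adjusted p = 0.1 with an estimated correlation). EdgeR called 506 genes higher and 471 lower, 208 in all with DESeq2 and 487 without section 1. How spots were marked is not stated, so genes used to mark them are no finding.

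Unmarked spots next to marked spots had higher interferon RNA than far spots. Cxcl10 rose by 1.17 ± 0.13, from 21.9 to 50.7 CPM, Isg15 by 0.77 ± 0.08, Ifit3b by 0.74 ± 0.08 and Irf7 by 0.72 ± 0.09. Of 33 interferon genes 17 rose and 0 fell (27 adjusted over the list alone), and of 25 cell cycle genes 8 rose and 0 fell (20 adjusted over the list alone), with Mki67 at 0.91 ± 0.14. Antigen presentation genes rose in 5 of 19 (11 adjusted over the list alone; camera adjusted p = 0.1 with an estimated correlation), with B2m at 0.32 ± 0.03. Homeostatic microglia genes rose in 5 of 20 (7 adjusted over the list alone; camera adjusted p = 0.26 with an estimated correlation), with C1qa at 0.22 ± 0.04. Trem2 differed by 0.02 ± 0.07 and Gfap by 0.12 ± 0.04, and neither passed. Oligodendrocyte markers fell in 10 of 12 (11 adjusted over the list alone), with Mobp at -0.38 ± 0.03 and Mbp at -0.36 ± 0.02. EdgeR called 159 genes higher and 130 lower. The count of 289 was 55 with DESeq2, and 161 and 173 without section 1 or 2.

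A hypothesis from the etoposide data is that long genes lost more RNA than short genes, as a block of topoisomerase II or of transcription along the gene may do. Across 13133 coding genes with a span in the RefSeq annotation of GRCm38, which are not independent replicates, log2 fold change and genomic span had a Spearman rho of -0.539. From the shortest to the longest of 5 equal groups of genes, with median spans of 4885 and 147725 bp, the median change went from 0.20 to -1.10. Abundance of long genes is argued against, as rho was -0.243 or lower in each of 5 groups of like abundance. Neuronal and synaptic genes are often long, and an effect of their function was not tested apart from span.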
